A study of Mus musculus with 40 samples.

How the data were processed

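RNA was sequenced from the livers of 40 mice. The labels divide them by genotype (wild type, WT, or homozygous deletion of exon 3 of the growth hormone receptor gene Ghr, d3), sex and diet (ad libitum, AL, or 40% calorie restriction, CR), with 5 mice in each of 8 groups. Per the labels, the diets began at weaning at 30 days and lasted 30 days, and the mice were killed at about 2 months. The extraction protocol in the labels gives 28 to 34 days instead, and the values do not settle which age holds. Each library is a separate mouse. Replicate numbers were given in the order of the records and pair nothing. The labels used here name no batch, collection day or collection time. The sample titles carry running numbers, whose meaning is not given. In CR males all WT numbers lie below all d3 numbers. Within d3 males and within d3 females all AL numbers lie below all CR numbers. Genotype in CR males and diet in d3 mice therefore cannot be separated from the order of these numbers.

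Per the submitters' processing notes, the tools were FastQC, MultiQC, Trimmomatic, kallisto and DESeq2, with the genome build GRCm38. Their versions, order and settings are not given in the sources used here. The authors deposited 1 table of normalized signal per gene, which holds read counts divided by a library factor. Dividing the deposited signal by the step between its lowest values gave whole reads, within a tolerance of 0.01, for 100% of the values in every library. In 2 libraries that step lay near 1, where a general check for whole reads could not tell it from rounding. The recovered totals were 21132490 to 44195300 reads per library, with a median of 36347580. The totals cover listed genes alone, since the lowest row total was 37 reads and rarer genes had been left out. Kallisto shares reads between near-identical transcripts by estimation, so levels of single members of the Mup, Cyp2, Cyp3a, Cyp4a, Sult2a and Serpina1 families are uncertain. The authors also deposited a log2 fold change and an adjusted p-value per gene for d3 against WT in each of the 4 combinations of sex and diet.

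The table has 17839 rows. Rows with the same symbol and the same 40 values as another row (115) were dropped, which left 17724 genes. Genes with a mean normalized value of at least 10 over the 40 libraries were tested (13776 genes). The tests were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(value + 1). All 8 groups were fitted in 1 model, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given with the standard error (SE). There were 12 comparisons of a pair of groups and 6 interactions. Gene positions are from GENCODE M21 on GRCm38, in which 17674 of the identifiers were found.

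The sex index of a liver is the mean log2 level of male-biased genes minus that of female-biased genes, scaled so that the females of the defining groups average 0 and the males 1. The sex-biased genes were chosen in the 10 defining mice alone (adjusted p under 0.05 and at least 2-fold, without Y-linked genes). In the 8 index comparisons the defining mice were never among those compared. Where the genotype shift in CR males is set against that in AL males, the WT AL males both define the index and are compared, so no p is given for that difference. For diet in d3 mice the defining mice were WT on AL, and for diet in WT mice they were d3 on AL. The 8 index comparisons used an exact 2-sided permutation test over all 252 splits of 10 livers, adjusted over the 8 tests. The smallest p that this test allows is 0.00794.

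Gene lists (31) were fixed from textbook knowledge before the data were examined, as were the designs, the rule for named genes and most alternatives. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The rule names Ghr always, then up to 10 genes with the largest increase and up to 10 with the largest decrease among called genes whose 2 groups of 5 do not overlap, and up to 4 called and 2 uncalled members of each list. For interactions it names up to 5 genes in each direction. Predicted genes are counted and not named. Some genes that the rule names are not reported here. Lists of skeletal muscle markers (16 measured) and exocrine pancreas markers (10 measured) were added after seeing the data.

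Alternatives fixed in advance were a pseudocount of 10, no filter on low values, an extra median-of-ratios scaling, a fit on the groups compared alone, library weights, leaving out each library in turn, and for the index a 4-fold minimum and fixed gene lists. Alternatives added after seeing the data were edgeR 4.0.16 (quasi-likelihood test with TMM scaling on the recovered reads of the same genes), leaving out the 17 libraries with a muscle level of at least 8 (mean log2), the muscle level as a covariate, and counts of gene lists without WT AL male replicates 4 and 5. The tests were checked on simulated data with 13636 genes. For d3 against WT CR males, limma recovered 61 of 100 genes changed 2-fold and 90 of 99 changed 4-fold, with 7 false calls. The simulation drew each gene independently around its group mean. It held no differences shared by many genes within a library, such as muscle transcripts, so its false calls need not hold for the real data. In the 80 pairs of replicates within groups, the chi-square statistic per gene between recovered reads was 27.3 to 692, so no pair looked like a library deposited in duplicate.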

Results

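The liver transcriptome was measured in mice that lack exon 3 of the growth hormone receptor gene (d3) and in wild-type mice (WT), in both sexes, fed ad libitum (AL) or held at 40% calorie restriction (CR). Each of the 8 groups had 5 livers. Recovered depth was 21132490 to 44195300 reads per library. Group means ran from 32533784 reads in WT AL males to 41093041 in d3 CR females. Ddx3y, a Y-linked gene, averaged 2440 ± 249 normalized counts (SD, n = 5) in WT AL males and 7.57 ± 3.68 (SD, n = 5) in WT AL females, and over all groups its lowest level in a male liver was 1543 and its highest in a female liver 15.4 normalized counts.

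Ghr (ENSMUSG00000055737, chromosome 15, 3317760 to 3583492 on the minus strand, GRCm38) encodes the growth hormone receptor. A gene-level value cannot show the deletion of exon 3 and does not check the genotype labels. Ghr averaged 15813 ± 3205 normalized counts in WT AL males and 14140 ± 2799 in d3 AL males (SD, n = 5 each). In CR males it averaged 17084 ± 2384 in WT and 12749 ± 1610 in d3 (SD, n = 5 each). In AL females the means were 12743 ± 3340 in WT and 11633 ± 3776 in d3, and in CR females 12080 ± 1839 and 11676 ± 2207 (SD, n = 5 each). Ghr was not called in any of the 18 comparisons. Its log2 change between genotypes was -0.42 ± 0.21 (SE) in CR males (limma adjusted p = 0.629).

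**Figure D1:**
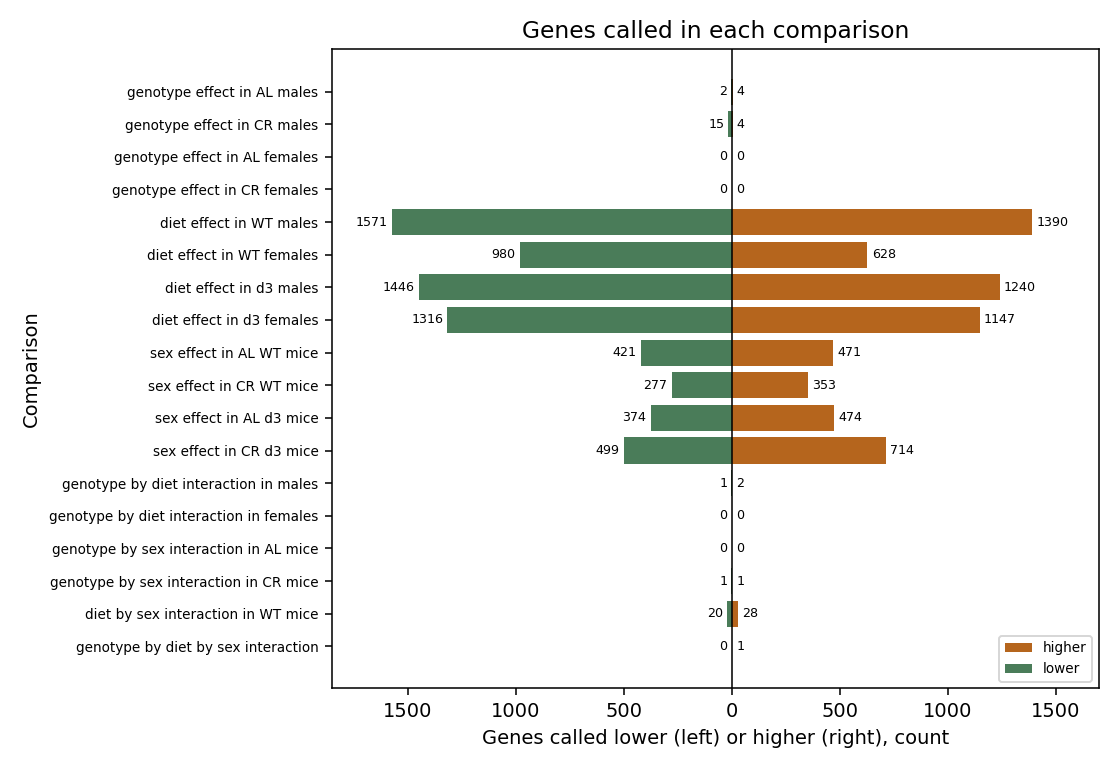
Number of genes called by limma (adjusted p under 0.05, 13776 genes tested) in each comparison, with genes higher in the first-named condition (CR, d3 or male) to the right and lower to the left. Diet called 1608 to 2961 genes and genotype 0 to 19.

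The first question was what the d3 genotype changes in the liver. In CR males, 3 named genes that are female-biased in mouse liver were higher in d3 than in WT, and male-biased genes were lower. Cyp2b13, a cytochrome P450, averaged 1401 ± 1124 normalized counts in d3 and 66.9 ± 55.6 in WT CR males (SD, n = 5 each), a log2 change of 4.44 ± 0.62 (SE; limma adjusted p = 0.000339). The sulfotransferase gene Sult3a1 rose by 3.55 ± 0.64 and Cyp2a4, a steroid hydroxylase, by 2.47 ± 0.45 on the log2 scale (SE). Serpina1e, which encodes a serine protease inhibitor of the alpha-1-antitrypsin family, fell from 16290 ± 20312 to 704 ± 370 normalized counts (SD, n = 5 each), a log2 change of -3.87 ± 0.59 (SE; limma adjusted p = 0.000699). WT CR male replicate 4 had 51834 and the other WT livers 2140 to 13910; without it the log2 change was -3.25 (limma adjusted p = 0.00429). Hsd3b5, a steroid dehydrogenase, changed by -4.40 ± 0.88, the major urinary protein genes Mup7 and Mup21 by -2.84 ± 0.56 and -2.47 ± 0.41, and the organic anion transporter gene Slco1a1 by -2.62 ± 0.53 (log2, SE). The complement genes C9 and C6 changed by -1.96 ± 0.42 and -1.79 ± 0.32, and Styk1, Susd4 and Insc by -1.85 ± 0.33, -1.49 ± 0.28 and -1.17 ± 0.22 (log2, SE). With each of the 10 livers left out in turn, C9 stayed called in 2 of 10 fits, Hsd3b5 and Slco1a1 in 5, Mup7 in 6, Insc in 7, Susd4 in 8, Cyp2a4 in 9 and the others in all 10, and all kept their sign. When the 10 CR males were fitted alone, of these 13 named genes Styk1 and Susd4 stayed called (adjusted p = 0.0499 for each) and the other 11 did not, Cyp2b13 (adjusted p = 0.221) and Serpina1e (adjusted p = 0.198) among them. Slco1a1 was not called by edgeR (adjusted p = 0.0658). Without WT CR male replicate 4 the change of Cyp2b13 was 3.77, and without d3 CR male replicate 2 or 5 that of Hsd3b5 was -3.66 or -5.00 (log2).

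In all, 19 genes were called in CR males, 4 higher and 15 lower in d3. Of 23 measured male-biased liver genes, 7 fell and 0 rose, and 17 fell when adjusted over the list alone; the list's camera adjusted p was 3.29e-32 and stayed at 0.000764 with an estimated correlation. Of 34 measured female-biased genes, 3 rose and 0 fell, and 8 rose when adjusted over the list alone (camera adjusted p = 5.13e-11; adjusted p = 0.0754 with an estimated correlation). Of 20 major urinary protein genes, 2 fell, and 15 fell when adjusted over the list alone (camera adjusted p = 6.22e-19; adjusted p = 0.0754 with an estimated correlation). Mup20 missed the threshold over all genes, at a log2 change of -1.69 ± 0.39 (SE; limma adjusted p = 0.0605). The count was 5 when the 10 CR males were fitted alone, 0 without the libraries rich in muscle transcripts, 651 (469 higher, 182 lower) with library weights, 11 without WT CR male replicate 2, 8 without replicate 4, 11 without replicate 5, and 10 without d3 CR male replicate 2. The authors' deposited table called 34 genes in this comparison, of which 18 were among the 19. The remaining gene, Serpina1e, had a log2 change of -4.30 there and no adjusted p.

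**Figure D2:**
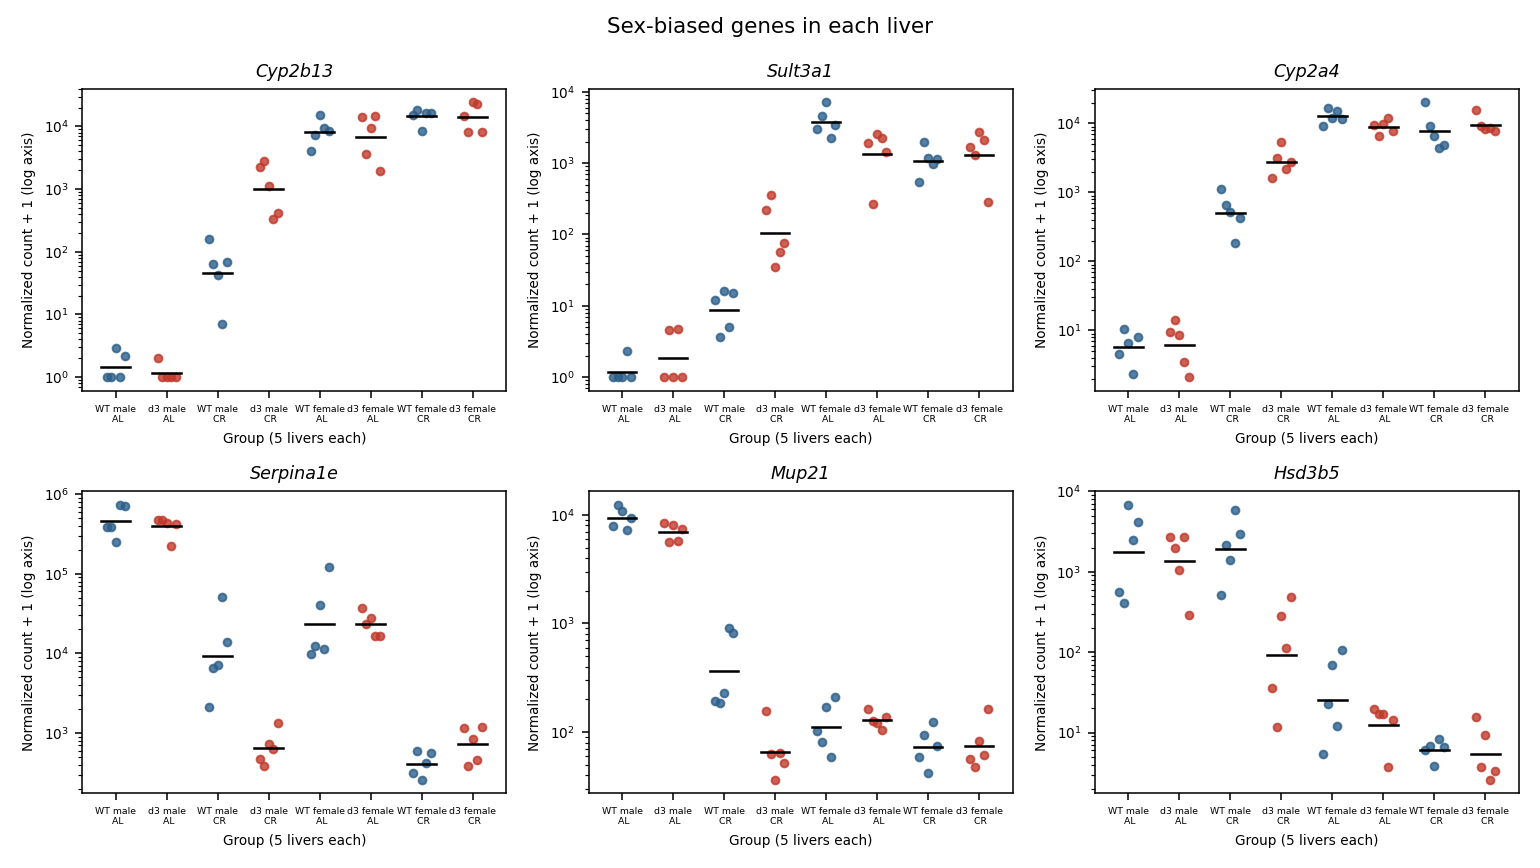
Normalized count + 1 (log axis) of 6 sex-biased genes in each of the 40 livers, with WT in blue, d3 in red and the bar at the mean of the log values. In CR males, Cyp2b13 averaged 1401 in d3 and 66.9 in WT, while Serpina1e averaged 704 and 16290, with 51834 in WT replicate 4.

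The sex index gave the position of each liver between the female and the male pattern. With genes chosen in WT AL mice (103 male-biased and 137 female-biased), WT CR males averaged 0.546 ± 0.074 and d3 CR males 0.317 ± 0.085 (SD, n = 5 each), and all 5 d3 livers lay below all 5 WT livers. The difference was -0.229 (exact permutation p = 0.00794, the smallest the test allows; adjusted p = 0.0212). Without the muscle-rich libraries it was -0.204, with 3 WT and 2 d3 livers left, too few for the test to reach 0.05. In AL males, with genes chosen in WT CR mice, the difference was 0.00300 (exact permutation p = 0.944). In females it was -0.00754 on CR (exact permutation p = 0.698) and 0.117 on AL (exact permutation p = 0.198). The genotype shift in CR males differed from that in CR females by -0.221 (exact permutation p = 0.00841 over 63504 pairs of splits). That p is for no genotype shift in either sex, so it does not test whether the 2 shifts are equal. The shift in CR males differed from that in AL males by -0.209 with the WT AL genes. No test is given for that value because the WT AL males also define that index.

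**Figure D3:**
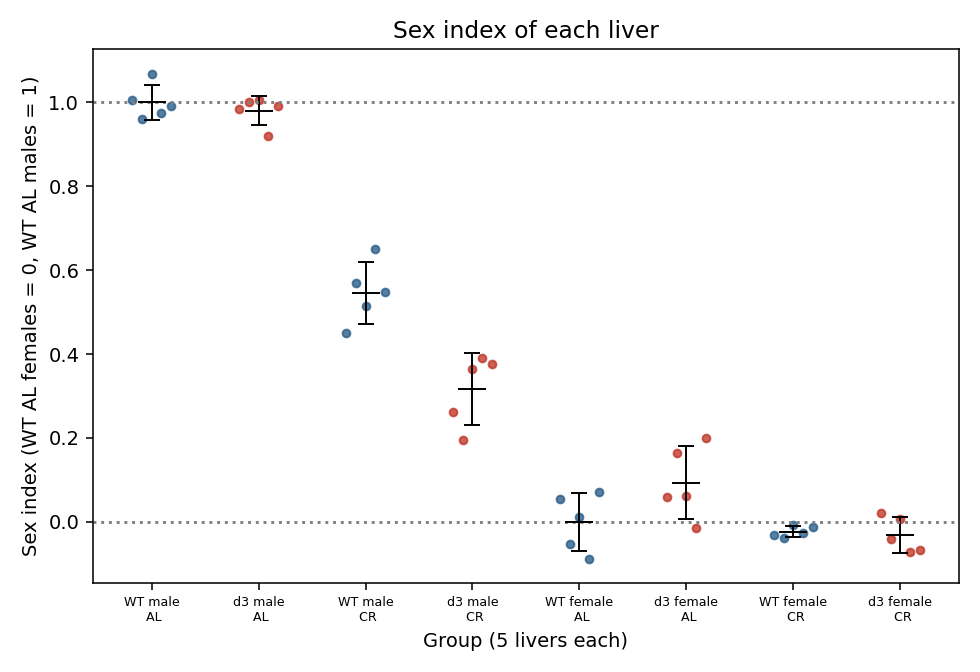
Sex index of each liver (no unit; WT AL females average 0 and WT AL males 1), with points for livers, a bar at the mean and the SD. WT AL mice define the index. CR males lie at 0.546 in WT and 0.317 in d3 on average, and d3 AL males at 0.980.

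In AL males, genes of the circadian clock were higher in d3. Ciart (ENSMUSG00000038550), a repressor in the clock, averaged 281 ± 173 normalized counts in d3 and 49.4 ± 30.9 in WT AL males (SD, n = 5 each), a log2 change of 2.52 ± 0.40 (SE; limma adjusted p = 0.00333). Dbp, a clock output transcription factor gene, rose by 2.77 ± 0.50 and the period gene Per3 by 1.38 ± 0.25 (log2, SE; limma adjusted p = 0.0153 for each). Dbp was 73.7 normalized counts in d3 AL male replicate 5, within the WT range of 28.8 to 276, and 899 to 1138 in the other 4 d3 livers; without replicate 5 its change was 3.51 (log2). Etv6, a transcription factor gene, fell from 987 ± 122 to 685 ± 101 normalized counts (SD, n = 5 each). The other 2 called genes lie outside the naming rule and were chosen after their values were seen: Tle3 changed by -0.93 ± 0.19 and Pias3 by 0.57 ± 0.11 (log2, SE). With each of the 10 livers left out in turn, Ciart stayed called in all 10 fits, Per3 in 5, Dbp and Etv6 in 4, and Tle3 and Pias3 in 3. Of 19 measured clock genes, 3 rose, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.87e-09; adjusted p = 0.00803 with an estimated correlation). Heat shock genes (12 measured) and unfolded protein response genes (14 measured) had median log2 changes of -0.76 and -0.53, with 0 members called over all genes and 0 and 6 lower when adjusted over the list alone. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.324 and adjusted p = 0.386). The mean log2 level of the unfolded protein response list was 13.39 and 12.80 in WT AL male replicates 4 and 5. It was 12.20 to 12.74 in the other WT livers and 12.01 to 12.34 in d3. That of the heat shock list was 13.16 and 12.64 in WT replicates 4 and 3. It was 11.38 to 11.75 in the other WT livers and 10.48 to 12.004 in d3. Both changes thus rested in part on these WT livers, and the lists were not tested here without them.

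The 6 genes called in AL males became 0 when the 10 AL males were fitted alone and 0 without the libraries rich in muscle transcripts, and 15 with edgeR. The count was 1 without d3 AL male replicate 1, replicate 4 or WT AL male replicate 5, 2 without d3 AL male replicate 2 or replicate 3, and 11 without WT AL male replicate 2. In females, limma called 0 genes between genotypes on AL (875 at an unadjusted p under 0.05) and 0 on CR (1027), and edgeR also called 0 and 0. The authors' deposited table called 54 genes in AL males, all 6 called here among them, 1 in AL females and 3 in CR females. Others of the 54, such as the acute phase genes Fga and Fgg, were lower in d3 and not called here (limma adjusted p = 0.452 and adjusted p = 0.427). Among AL males the acute phase level was highest in WT replicates 4 and 5, and the authors' calls were not tested without them. The interactions tested whether the genotype change differed between groups. In males limma called 3 genes for a difference with diet, Tle3 (1.49 ± 0.27), Ciart (-2.94 ± 0.56; log2, SE) and Cyp2b13. Of these, edgeR called Tle3 and not Ciart (adjusted p = 0.102) or Cyp2b13 (adjusted p = 1). Cyp2b13 had 0 to 1.88 normalized counts in AL males, too few for a genotype ratio on AL, so no size is given for it. When the groups compared were fitted alone, all 3 calls were lost (adjusted p = 0.221 for Tle3, 0.0507 for Ciart and 0.301 for Cyp2b13) and 1 other gene was called. Of the 23 male-biased genes, 0 were called in this interaction, and 14 were lower when adjusted over the list alone (camera adjusted p = 1.4e-22; adjusted p = 0.00782 with an estimated correlation). In CR mice it differed with sex for Serpina1e, at -4.70 ± 0.83, and for Ppfibp1, at 0.64 ± 0.12 (log2, SE); both calls were lost when the groups compared were fitted alone (adjusted p = 0.111 for each) and without the muscle-rich libraries (adjusted p = 0.189 and adjusted p = 0.171), where 1 other gene was called. Tle3 was the 1 gene called in the interaction of all 3 factors, at 2.18 ± 0.38 (log2, SE). Without the muscle-rich libraries its value was 1.78 and the call was lost (adjusted p = 0.197), while 1 gene was called in the other direction. The remaining genotype interactions called 0 genes with limma and 0 with edgeR, with 1527 (diet, in females) and 1056 (sex, on AL) at an unadjusted p under 0.05. Several of these calls lay near the threshold and were lost with single libraries, while the changes kept their sign: with 1 library left out, the change ran from 1.32 to 1.64 for Tle3 and from -3.24 to -2.63 for Ciart in the male diet interaction, from -5.23 to -4.08 for Serpina1e and from 0.590 to 0.683 for Ppfibp1 in the CR sex interaction, and from 2.01 to 2.33 for Tle3 with all 3 factors (log2). Ppfibp1 was not called with the muscle covariate (adjusted p = 0.0514). With library weights the sex interaction on CR called 374 genes, the one on AL 5, the diet interaction in females 2 and the 3-factor one 3, and without the muscle-rich libraries the male diet interaction called 0. The male diet interaction called 0 genes without WT AL male replicate 5, d3 AL male replicate 2 or 3, WT CR male replicate 2 or 4, or d3 CR male replicate 1, 2 or 3, and 5 without d3 CR male replicate 4. In CR mice the sex interaction called 0 genes without WT CR female replicate 1 or 4, WT CR male replicate 5, d3 CR female replicate 1 or 3, or d3 CR male replicate 1, 2 or 3, and 1 without WT CR male replicate 2 or 3 or WT CR female replicate 2 or 5. It called 4 without WT CR female replicate 3 or d3 CR female replicate 4, 6 without d3 CR male replicate 4 and 15 without d3 CR female replicate 5. The 3-factor interaction called 0 genes without WT AL male replicate 4, WT AL female replicate 5, WT CR male replicate 1, WT CR female replicate 4, d3 AL male replicate 2, d3 AL female replicate 2, d3 CR male replicate 1 or 3, or d3 CR female replicate 5, and 2 without WT AL female replicate 1. The AL sex interaction called 1 gene without WT AL male replicate 1, d3 AL male replicate 2 or d3 AL male replicate 5.

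The next question was what calorie restriction changes. In males, female-biased genes rose and male-biased genes fell on CR. In WT males, Cyp2b9 rose from 17.7 ± 33.3 to 7277 ± 3443 normalized counts and Cyp2a4 from 5.43 ± 3.19 to 584 ± 351 (SD, n = 5 each). Mup7 fell from 1386470 ± 182861 to 20782 ± 15941 and Serpina1e from 494741 ± 214813 to 16290 ± 20312 normalized counts (SD, n = 5 each). In d3 males, Cyp2a4 rose by 8.83 ± 0.45 and Cyp2b9 by 12.77 ± 0.81, while Mup7 changed by -9.21 ± 0.56 and Serpina1e by -9.27 ± 0.59 (log2, SE). Of 23 male-biased genes, 15 fell in WT males and 19 in d3 males (17 and 20 adjusted over the list alone). Of 34 female-biased genes, 14 rose and 1 fell in WT males and 17 rose and 1 fell in d3 males (16 and 19 rose adjusted over the list alone). Of 20 major urinary protein genes, 17 fell in WT males and 20 in d3 males (18 and 20 adjusted over the list alone; adjusted p = 0.0404 and adjusted p = 0.00443 with an estimated correlation). With an estimated correlation the male-biased list held in both (adjusted p = 0.0482 in WT and adjusted p = 0.00178 in d3), and the female-biased list in d3 (adjusted p = 0.0223) but not in WT (adjusted p = 0.145). The sex index fell on CR by 0.345 in WT males and by 0.663 in d3 males (exact permutation p = 0.00794 and adjusted p = 0.0212 for each). The defining mice were d3 on AL for WT and WT on AL for d3, so these values are on different scales. With WT AL mice defining the index for both, WT males averaged 1 on AL, by definition, and 0.546 on CR, and d3 males 0.980 and 0.317. In females, with the same defining mice for each genotype, the index changed by 0.0210 in WT (exact permutation p = 0.484). In d3 females it changed by -0.125 (exact permutation p = 0.0238, adjusted p = 0.0476). The call in d3 females was lost without d3 AL female replicate 1, 2, 3 or 5 or d3 CR female replicate 2, 3, 4 or 5, where the value ran from -0.0980 to -0.134. Without the muscle-rich libraries the change was -0.374 in WT males (adjusted p = 0.0571), -0.652 in d3 males and -0.102 in d3 females, the last 2 with 5 livers left, too few for the test to reach 0.05. The WT males left, 4 on AL and 3 on CR, did not overlap, so their permutation p was the smallest the test could give there.

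The clock genes changed on CR in all 4 pairs of groups. In WT males, Arntl, a core activator of the clock, fell from 1021 ± 246 to 19.8 ± 15.9 normalized counts, Per3 rose from 128 ± 69.5 to 2381 ± 164 and Dbp from 122 ± 105 to 7439 ± 950 (SD, n = 5 each). Clock, the partner of Arntl, changed by -2.21 ± 0.12 (log2, SE). In WT females Dbp rose by 7.06 ± 0.50 and Per3 by 4.82 ± 0.25, while Npas2 and Arntl changed by -4.80 ± 0.46 and -3.92 ± 0.36 (log2, SE). In d3 females the changes were 6.51 ± 0.50 for Dbp, 4.39 ± 0.25 for Per3, -5.02 ± 0.46 for Npas2 and -4.27 ± 0.36 for Arntl (log2, SE). Of 19 measured clock genes, 14 rose and 5 fell in WT males, 12 and 5 in WT females, 11 and 4 in d3 males, and 11 and 5 in d3 females. Adjusted over the list alone, 14 and 5, 13 and 5, 13 and 4, and 13 and 5 did so. With an estimated correlation the list held in WT females (adjusted p = 0.0469) and not in WT males (adjusted p = 0.0695), d3 males (adjusted p = 0.608) or d3 females (adjusted p = 0.589). Collection times are not given in the sources used here, so an effect of diet on the clock and a different collection time cannot be told apart.

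**Figure D4:**
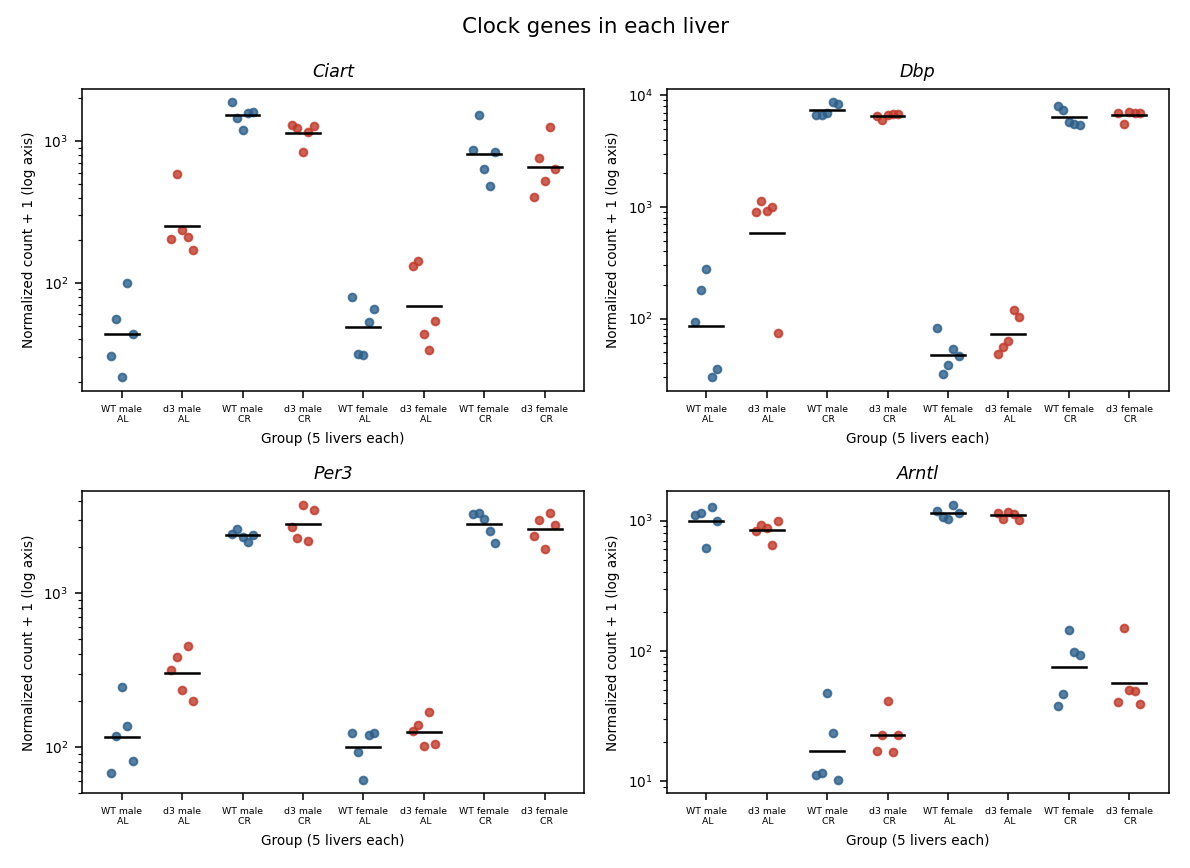
Normalized count + 1 (log axis) of 4 clock genes in each of the 40 livers, with WT in blue, d3 in red and the bar at the mean of the log values. Arntl averaged 1021 in WT AL males and 19.8 in WT CR males, and Ciart 281 in d3 AL males and 49.4 in WT AL males.

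Genes of lipid synthesis rose on CR. In WT males, Thrsp, a regulator of fatty acid synthesis, rose from 647 ± 506 to 16411 ± 5127 and Srebf1, a transcription factor gene of the same pathway, from 1547 ± 363 to 12268 ± 2718 normalized counts (SD, n = 5 each). Of 15 measured fatty acid synthesis genes, 10 rose in WT males, 10 in d3 males, 8 in WT females and 7 in d3 females, and 0 fell. Adjusted over the list alone, 12, 13, 10 and 9 rose, and 1 fell in each group of males. With an estimated correlation this list held in WT males (adjusted p = 0.0404) and d3 males (adjusted p = 0.00768) and not in WT females (adjusted p = 0.178) or d3 females (adjusted p = 0.589). Of 22 cholesterol synthesis genes, 13 rose in WT males, 18 in d3 males, 10 in WT females and 16 in d3 females (15, 19, 17 and 17 adjusted over the list alone); all 4 camera calls were lost with an estimated correlation (lowest adjusted p = 0.427). Fatty acid oxidation genes went the other way in WT males, where 11 of 26 fell and 0 rose (11 also when adjusted over the list alone), among them the lipid droplet gene Plin2 (-1.82 ± 0.27), the carnitine transferase gene Cpt2 (-0.92 ± 0.16) and the hormone gene Fgf21 (-3.18 ± 0.71, and -2.56 without WT CR male replicate 1; log2, SE); that list had adjusted p = 0.478 with an estimated correlation, and 17 fell without WT AL male replicates 4 and 5.

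Acute phase and protein folding genes were lower on CR in WT males. This rested largely on 2 AL livers for acute phase genes and in part on them for folding genes. Of 18 acute phase genes 13 fell, also when adjusted over the list alone (adjusted p = 0.427 with an estimated correlation). The mean log2 level of this list was 16.2 in WT AL male replicate 4 and 14.3 in replicate 5, which also had the highest neutrophil marker levels of the group (6.53 and 6.02), against 12.1 to 12.3 in the other 3 and 11.5 to 12.2 on CR. Without these 2 livers 3 acute phase genes fell and 2 rose, and the median log2 change of the list went from -1.02 to -0.25. Saa1, an acute phase protein gene, averaged 83446 ± 161465 normalized counts in WT AL males and 297 ± 91.4 in WT CR males (SD, n = 5 each), with a spread between the AL livers larger than their mean. Of 14 unfolded protein response genes, 10 fell in WT males, also when adjusted over the list alone, among them Hspa5, the main chaperone of the endoplasmic reticulum, from 47902 ± 15113 to 20140 ± 2528 normalized counts (SD, n = 5 each; list adjusted p = 0.427 with an estimated correlation), and 5 fell without the same 2 livers. In d3 females, 6 of 12 heat shock genes fell, 7 when adjusted over the list alone, among them Hsp90aa1 (-1.66 ± 0.32, log2, SE; list adjusted p = 0.589 with an estimated correlation). Gsta1, a glutathione transferase gene, rose by 4.27 ± 0.87 in WT males, 5.78 ± 0.87 in WT females and 4.98 ± 0.87 in d3 females (log2, SE), and by 3.33 in WT males without WT AL male replicate 1, 5.11 in WT females without WT AL female replicate 1 and 4.29 in d3 females without d3 AL female replicate 5.

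Limma called 2961 genes for diet in WT males (1390 higher, 1571 lower on CR), 1608 in WT females (628 and 980), 2686 in d3 males (1240 and 1446) and 2463 in d3 females (1147 and 1316). Without the libraries rich in muscle transcripts the counts were 557 in WT females, 1127 in d3 males and 1042 in d3 females, fitted on their own 10 livers 978 in WT and 1117 in d3 females, and with library weights 2674 in WT females and 4111 in d3 males. The diet change differed between WT males and females for 48 genes (28 higher, 20 lower in males). Among these, Cyp2b9 differed by 10.47 ± 1.15, Cyp2a4 by 7.17 ± 0.64, Mup7 by -4.72 ± 0.79, Mup21 by -4.09 ± 0.58 and Clock by -0.99 ± 0.17 (log2, SE). The count was 106 without WT AL female replicate 1 23 without the muscle-rich libraries, 91 with the muscle covariate and 329 with library weights.

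The sexes were compared within each genotype and diet. In WT AL mice, the fatty acid hydroxylase gene Cyp4a12a averaged 14858 ± 4023 normalized counts in males and 6.67 ± 5.29 in females, and Mup20 280238 ± 78827 and 2525 ± 951 (SD, n = 5 each). Cyp3a41a averaged 4.87 ± 3.79 in males and 62941 ± 20124 in females, and Cyp2a4 5.43 ± 3.19 and 12923 ± 3077 normalized counts (SD, n = 5 each). The prolactin receptor gene Prlr was lower in males by -1.50 ± 0.28 and the oxysterol hydroxylase gene Cyp7b1 higher by 3.58 ± 0.31 (log2, SE). In WT CR mice, Cyp4a12b averaged 625 ± 297 in males and 1.66 ± 2.33 in females, and Sult2a1 0.176 ± 0.393 and 16295 ± 11029 normalized counts (SD, n = 5 each). In d3 CR mice, Mup20 averaged 7933 ± 3049 in males and 2355 ± 1208 in females (SD, n = 5 each). Of 23 male-biased genes, 22 were higher in males in WT AL mice, 20 in WT CR, 21 in d3 AL and 12 in d3 CR mice (22, 21, 22 and 12 adjusted over the list alone). With an estimated correlation this list held in WT AL (adjusted p = 1.83e-06), WT CR (adjusted p = 6.17e-05) and d3 AL mice (adjusted p = 3.43e-06) and not in d3 CR mice (adjusted p = 0.0943). Of 34 female-biased genes, 29, 21, 25 and 15 were lower in males in the same order (30, 23, 27 and 18 adjusted over the list alone), and the list held in all 4 with an estimated correlation (highest adjusted p = 0.0237). In d3 CR mice 6 of 15 fatty acid synthesis genes were higher in males, 9 when adjusted over the list alone, among them Gpam (1.00 ± 0.18), Acly (1.39 ± 0.28) and Acaca (1.15 ± 0.26; log2, SE), with adjusted p = 0.097 for the list with an estimated correlation.

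Limma called 892 genes between the sexes in WT AL mice (471 higher, 421 lower in males), 630 in WT CR mice (353 and 277), 848 in d3 AL mice (474 and 374) and 1213 in d3 CR mice (714 and 499). Fitted on their own 10 livers, WT AL mice had 454 calls, WT CR mice 382 and d3 CR mice 100. Without the muscle-rich libraries WT CR mice had 61 genes higher and 47 lower in males, and with library weights the 4 counts were 1513, 1759, 1913 and 2088. The WT CR count was 348 without WT CR female replicate 3, 359 without female replicate 4, 402 without female replicate 5 and 325 without WT CR male replicate 4, and the d3 CR count was 494 without d3 CR male replicate 5, 789 without male replicate 3 and 781 without d3 CR female replicate 4.

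Markers of skeletal muscle were measured in the same libraries. Their mean log2 level ran from 0.917 to 16.4, and 17 of 40 libraries were at 8 or more. Libraries at 8 or more occurred in every group, from 1 of 5 in WT AL males to 3 of 5 in d3 CR males and d3 CR females. None of 16 muscle markers and none of 10 exocrine pancreas markers was called in any of the 18 comparisons. The muscle list had a median log2 difference of 3.78 between d3 and WT CR females (camera adjusted p = 0.000832; adjusted p = 0.688 with an estimated correlation), and the pancreas list one of -2.39 between d3 and WT AL males (camera adjusted p = 0.000214; adjusted p = 0.358 with an estimated correlation). The pancreas level was 12.3 in WT AL male replicate 5, 0.889 to 1.63 in the other WT AL males and 1.10 to 1.52 in d3, and without that library the list had a mean log2 difference of -0.00618.

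**Figure D5:**
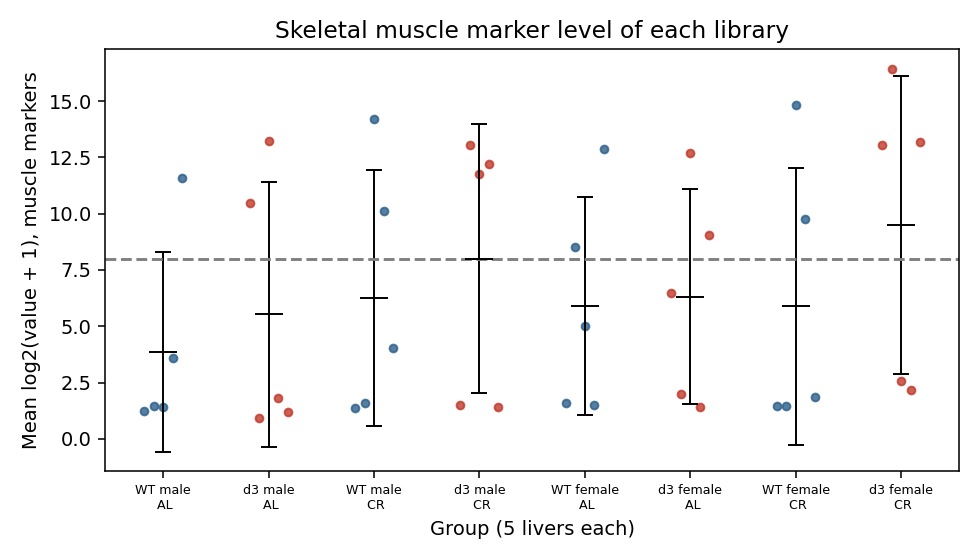
Mean log2(value + 1) of 16 skeletal muscle markers in each library, with the mean and SD of each group; the dashed line is at 8. Libraries above the line occur in all 8 groups, 17 in total.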

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

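All explanations weighed here, and the counts of splits, were tested with predictions set down only after the results had been seen, although the sex index comparison itself had been fixed before the data were examined. The muscle markers, the limit of 8 and the family list were likewise chosen after seeing the data.

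The first pattern is a skeletal muscle marker level at or above the limit in 17 of the 40 livers. Some livers below the limit also held muscle transcripts. The level was 6.48 in d3 AL female replicate 1 and 4.99 in WT AL female replicate 3. The fits without muscle-rich libraries are thus not free of muscle transcripts. Among the 17 at or above the limit, muscle genes of a second list (13 measured) followed the marker level. The median over genes was 0.971 for Pearson r and 0.973 for Spearman rho (permutation p = 1e-05 for each, the smallest they can give). Without the 2 farthest libraries r was 0.976. Muscle tissue carried along with the liver would give such a value, which may reflect dissection. Any other source of muscle RNA would give it too, so the value does not settle the source. Genotype, diet or sex as the whole cause is argued against, since all 8 groups held libraries both above and below the limit. Muscle-rich libraries numbered 10 of 20 in d3 and 7 of 20 in WT (Fisher's exact p = 0.523), which leaves a partial group difference open.

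The second pattern is the lower level of male-biased genes and higher level of female-biased genes in d3 than in WT CR males. With the muscle level as a covariate, all 19 called genes were still called, which argues against muscle content as the cause, although leaving out the 17 muscle-rich libraries, with 2 and 3 livers left in the groups, gave 0 calls. Reads shared between copies cannot account for the 6 called genes outside multigene families, while for the 13 in such families that stays open. The sex index, from genes chosen in other mice, differed by -0.229, so a shift of the whole sex-biased programme with genotype remains a hypothesis. Litter, cage, collection time and the order of the sample numbers, which separates d3 from WT CR males fully, were not tested. Among 100 splits of the 10 CR males, 2 gave at least 19 genes, the real one included. The highest other split gave 607 genes, with 4 muscle-rich livers on one side and 1 on the other. A split that mixes the genotypes can thus call more genes than the real groups, so the count does not exclude chance. Whether muscle content lies behind the 607 genes was not tested.

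The third pattern is the higher level of clock genes in d3 than in WT AL males. Across 19 clock genes, which are not independent replicates, this change had a Pearson correlation of 0.889 (Spearman 0.911) with the CR change in WT females, who share no library with it. Livers collected at different clock times and a genotype effect on the clock cannot be told apart, because both give such a value and no collection time is labelled. The mean size of the log2 change of the 11 clock genes past the threshold over the list alone was 1.23. It stayed at 1.09 or more with any 1 library left out. Those genes were chosen in the same livers, so this cannot decide whether a single library is the cause. The mean log2 level of the whole clock list was 9.36 in d3 AL male replicate 5 and 9.69 to 9.96 in the other d3 AL males. It was 8.72 to 9.44 in WT AL males. Among 100 splits of the 10 AL males, 2 gave at least 6 genes, the real one included, and the highest other gave 6.

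For diet, 1 of 100 splits, the real one, reached the real count in WT males (2961; highest other 608), WT females (1608; 247), d3 males (2686; 1143) and d3 females (2463; 738). For sex the number was 1 in WT AL mice (892; highest other 531), 2 in WT CR mice (630; 1183), 1 in d3 AL mice (848; 206) and 1 in d3 CR mice (1213; 645). In WT CR mice another split thus called more genes than the real one, so chance is not excluded there. Each of the other diet and sex counts was the highest among its 100 splits. The counts of splits were not adjusted for the number of comparisons. For genotype in AL and CR females all 100 splits reached the real count of 0, with highest others of 10 and 1511; in the split with 1511, 5 muscle-rich livers stood on one side and 0 on the other.

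Some changes differed between groups. By limma, the genotype change differed with diet in males for 3 genes (4 of 100 splits reached 3, highest other 318) and with sex in CR mice for 2 genes (3 of 100, 86). The diet change differed with sex in WT mice for 48 genes (4 of 100, 921). All interaction splits shuffled genotype within each sex and diet, or diet within each sex for the diet by sex count. They removed any effect of genotype or diet as a whole, so they cannot decide whether that effect differs between groups. For the interaction of all 3 factors, 1 gene was called and 7 of 100 splits gave as many (highest other 61), so chance was not excluded. For the genotype by diet interaction in females and the genotype by sex interaction in AL mice, all 100 splits reached 0, with highest others of 494 and 11. The sex index shift with genotype in CR males differed by -0.221 from that in CR females and by -0.209 from that in AL males, where WT AL males both define the index and are compared. Neither difference was tested against equal shifts.

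Of 56 groups of 5 values examined for a single distant library (7 measures), 10 had one, where chance gives about 1 in 20. Depth was 21132490 reads in WT AL male replicate 3 against 33529433 to 36482554 in the others. The sex index was 0.919 in d3 AL male replicate 4 against 0.984 to 1.01. The muscle level was 11.6 in WT AL male replicate 5 against 1.23 to 3.59. The acute phase level was 11.5 in WT CR male replicate 3 against 12.1 to 12.2. The exocrine pancreas level (mean log2) was 5.30 in d3 AL female replicate 1, 5.11 in d3 CR male replicate 4, 12.3 in WT AL male replicate 5 and 7.50 in WT CR male replicate 3, against at most 2.08 in the other libraries of those groups. Ghr (log2) was 12.8 in WT AL female replicate 1 against 13.7 to 13.9, and 13.1 in WT CR female replicate 3 against 13.6 to 13.7.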

How the results depend on the processing

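The edgeR test, the fits without muscle-rich libraries and the muscle covariate were chosen after seeing the data. So were the gene list counts without WT AL male replicates 4 and 5. The other settings were chosen before. All 18 gene counts stayed within 1.5 times the reported count with a pseudocount of 10, without the filter and with rescaled libraries. The causes of the changes below were not tested, except that fits on the compared groups or without muscle-rich libraries used fewer livers. With library weights, genotype in CR males called 651 genes (469 higher, 182 lower, against 4 and 15), diet 2674 in WT females and 4111 in d3 males, and sex 1513 in WT AL, 1759 in WT CR, 1913 in d3 AL and 2088 in d3 CR mice. The interactions with weights called 2 (genotype by diet, females), 5 (genotype by sex, AL), 374 (genotype by sex, CR), 329 (diet by sex) and 3 genes (all 3 factors). With the compared groups alone, genotype called 0 in AL males and 5 in CR males, diet 978 in WT females and 1117 in d3 females, sex 454 in WT AL, 382 in WT CR and 100 in d3 CR mice, genotype by diet 1 in males (not among the 3 reported) and genotype by sex 0 in CR mice. Without muscle-rich libraries, genotype called 0 in AL and 0 in CR males, diet 557 in WT females, 1127 in d3 males and 1042 in d3 females, sex 1.1e2 in WT CR mice (61 higher, 47 lower), genotype by diet 0 in males, genotype by sex 1 in CR mice (not among the 2 reported) and diet by sex 23. The covariate gave 1 for genotype by sex in CR mice and 91 for diet by sex. By edgeR, genotype in AL males called 15 and genotype by diet in males 1.

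Without muscle-rich libraries the sex index changed by -0.2036 with genotype in CR males, by -0.374, -0.6515 and -0.1023 with diet in WT males, d3 males and d3 females, and by -0.008901 with genotype in AL males. Of these, genotype in CR males and diet in d3 males and d3 females kept 5 livers, too few to reach 0.05. Diet in WT males, with 4 and 3 livers left, was at the smallest p the test could give. Genotype in AL males gave -0.01157 with 4-fold genes, -0.01812 with fixed lists and -0.008082 with a pseudocount of 10. Diet gave -0.02966 in WT females with 4-fold genes, -0.09964 with fixed lists, and -0.1729 in d3 females with fixed lists. Of 165 gene list calls, 24 held with an estimated correlation.

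Leaving out 1 library gave 1 to 11 genes for genotype in AL males and 8 to 28 in CR males, 325 to 885 for sex in WT CR and 494 to 1506 in d3 CR mice, and for the interactions 0 to 5 (genotype by diet, males), 0 to 1 (genotype by sex, AL), 0 to 15 (genotype by sex, CR), 37 to 106 (diet by sex) and 0 to 2 (all 3 factors). The index ran from -0.009623 to 0.03351 (genotype, AL males), -0.02043 to 0.002897 (genotype, CR females) and -0.1519 to -0.09804 (diet, d3 females). Over 562 pairs of a named gene and a comparison, 10444 alternative values held 9517 with the same call, 874 no longer past the threshold, 5 newly past it, 48 uncalled ones of the other sign and 0 called ones of the other sign. No paired analysis was possible because replicate numbers follow the order of the records and link no animals. Depth limits genes with few reads, since the tested genes had a mean of at least 10 normalized counts.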

Other observations

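Genes of glucose handling and drug metabolism also changed on CR, where diet was not separated from clock phase. Pklr, the liver pyruvate kinase gene, rose from 2279 ± 355 to 14736 ± 6767 normalized counts in WT males, Gys2, the liver glycogen synthase gene, from 5534 ± 1025 to 14701 ± 2352, and Slc2a2, the glucose transporter gene of liver, from 7224 ± 1281 to 21090 ± 5306 (SD, n = 5 each). In d3 males Pklr rose by 2.70 ± 0.33 and Slc2a2 by 1.60 ± 0.25, while G6pc, which encodes glucose-6-phosphatase, changed by -1.98 ± 0.41 (log2, SE). Of 18 gluconeogenesis and glycolysis genes, 6 rose and 0 fell in WT males and 5 rose and 1 fell in d3 males (10 and 7 rose, 1 and 3 fell adjusted over the list alone; adjusted p = 0.427 and adjusted p = 0.768 with an estimated correlation). Of 28 xenobiotic metabolism genes, 13 rose and 1 fell in WT males and 13 rose in d3 males (20 and 14 rose, 1 and 0 fell adjusted over the list alone; adjusted p = 0.427 and adjusted p = 0.653 with an estimated correlation), among them the glutathione transferase genes Gsta4, by 1.83 ± 0.34, and Gstm3, by 3.39 ± 0.68, in WT males (log2, SE). In females, Cyp2b10 changed by -3.49 ± 0.51 in WT and by -2.68 ± 0.51 in d3 (log2, SE).

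Cux2, a female-biased transcription factor gene of liver, rose from 206 ± 58.1 to 1183 ± 928 normalized counts on CR in d3 males (SD, n = 5 each) and by 1.51 ± 0.45 in WT females (edgeR adjusted p = 0.0505) and 1.98 ± 0.45 in d3 females (log2, SE). The insulin receptor substrate gene Irs1 changed on CR by -1.08 ± 0.23 in WT males, -0.68 ± 0.23 in d3 males (edgeR adjusted p = 0.0575) and -0.76 ± 0.23 in d3 females (log2, SE). Among cell cycle genes, the mitotic kinase gene Aurka fell in all 4 pairs of groups, by 0.80 in WT males, by 0.95 in WT females, by 0.95 in d3 males and by 1.09 in d3 females on the log2 scale, while Mcm6, a replication helicase gene, changed by 1.04 ± 0.19 in WT males and 1.55 ± 0.19 in d3 males (log2, SE).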
